A study of Raphidocelis subcapitata with 493 samples.

How the data were processed

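Gene expression was measured in 493 libraries of the unicellular green alga Raphidocelis subcapitata, made with a 3' tag kit that reads near the polyadenylated end of each transcript and adds a random molecular identifier. Per the labels' protocols, RNA came from pooled homogenates of wells on deep 96-well plates, and each well held 0.33% solvent. The deposited files are 22 tables of whole-number counts, one per compound, with the same 13429 gene identifiers in the same order. Per the submitters' processing notes the tools were fastp 0.23.2, STAR 2.7.10a, SAMtools 1.15.1 and featureCounts 2.0.6. The genome build, the annotation and whether reads sharing a molecular identifier were collapsed are not given in the sources used here. If they were not collapsed, part of each count is amplification, and the counting precision is lower than the totals imply. The kit reads one end of the transcript, so a count needs no correction for gene length, and genes that overlap or have near-identical copies can share reads.

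Groups were taken from the labels, which give the compound, the nominal concentration and a number P1, P2 or P3 for each library. Every exposure held 2 compounds and 3 control libraries labelled DMSO. The control columns were identical in both tables of an exposure for 33 of 33 libraries, so comparisons of both compounds with the control share its chance values. The series text names DMSO or methanol as solvent, while the control labels name DMSO alone; no methanol control was analysed here. The copper sulfate positive controls, the lowest planned dilution and the plate kept for phenotypes were not analysed here. No column was left unmapped. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

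Replicates of a group differed by more than counting noise in each of 491 pairs, with a chi-square per degree of freedom from 1.73 to 17.63 over genes with a summed count of at least 20. No library was treated as a duplicate. The totals ran from 259836 to 2470296 counts, and no total was under 20% of the median of its table, so the planned removal of shallow libraries removed nothing.

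The comparisons and their tests were chosen before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr by group, TMM normalisation, estimateDisp, robust glmQLFit and glmQLFTest), and p-values were adjusted by Benjamini-Hochberg over the genes of one fit. Genes with an adjusted p under 0.05 were called changed. Each compound was fitted with all its concentrations and its own controls, and each concentration was compared with the control. A trend was tested as a linear term in the rank of the concentration, with the control at rank 0. Compounds of one exposure were contrasted directly at their highest shared concentration (11 contrasts). For 6 related pairs from different exposures, the difference of their changes against their own controls was tested. Recurrence was counted over the 11 exposures and set against 1000 random draws of lists of the same sizes within 10 bins of mean expression.

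Points of departure came from genes with an adjusted trend p under 0.05 and a change of at least 1.5-fold at some concentration. Linear, power, saturating exponential and Hill curves were fitted to log2 CPM (prior count 2), and the curve with the lowest AIC was kept if it beat a constant. The benchmark concentration was where the curve left its start by 1 residual SD. The point of departure was the 10th percentile of these concentrations if at least 20 genes remained. Its 95% interval came from 2000 resamplings of the genes and covers only which genes were summarised. Leaving out each replicate number in turn shows how far the value depends on the libraries. Those fits use fewer libraries and can call other genes, so their range is not an error around the full value. For FC10diol the full value of 1.89 µM lay above its range of 1.45 to 1.79 µM.

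The files give gene identifiers without names, and no annotation was used here. The 26 gene lists chosen beforehand could therefore not be matched and were not tested. The rule for named genes, set at the same time, then allows at most 2 identifiers that rose and 2 that fell, taken in order from the genes called in the most exposures. Ties were broken by the mean size of the called log2 fold changes. Fold changes of these genes are printed in full for the compound with the largest change among those with a mean of at least 10 counts in both groups, a minimum chosen after their values were seen.

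The alternatives chosen beforehand were RLE size factors, no filter on low counts, DESeq2 1.42.0, the replicate number as a covariate, leaving out each replicate number, and other definitions of the point of departure. Those added after seeing the data were library totals without scaling factors, no 10 µM libraries, contrasts with the lowest concentration in place of the control, no control libraries, differences of changes for the compound pairs, a replicate covariate for the points of departure and the 10 µM contrast, leaving out single controls of the PFOA and PFOS exposure, and all alternatives of the recurrence.

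The tests were run on simulated counts with 200 changed genes. For FHxSA at the highest concentration (9482 genes), edgeR recovered 37.3% of 1.5-fold, 74.6% of 2-fold and 92.4% of 4-fold changes, with 2.9% false calls. For the shallower PFNA table (7752 genes), it recovered 7.5%, 28.4% and 81.8%, with 4.9% false calls. The trend test of FHxSA recovered 52.2%, 88.1% and 98.5%, with 7% false calls. The contrast of FHxSA with N-EtFOSA-M (9660 genes) recovered 25.4%, 50.7% and 90.9%, with 5.1% false calls. The difference of changes of 6:2FTS and 8:2FTS (9455 genes) recovered 6%, 46.3% and 69.7%, with 1.2% false calls. Simulated benchmark concentrations of 0.143, 1.43 and 7.14 µM were estimated at medians of 0.167, 1.77 and 7.97 µM. These genes shared the same curve shape with normal noise and a maximum change of 4-fold. Called changes were smaller, for instance a median of 0.62 on the log2 scale with FHxSA at the highest concentration. The simulation covers neither the 10th percentile over genes nor values below the lowest tested concentration of 0.1 µM. Of 2000 simulated flat genes, 23% received a benchmark concentration from the curve fit alone, before any trend filter.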

Results

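Cultures of Raphidocelis subcapitata, a freshwater green alga used in toxicity testing, were exposed for 24 h to 22 per- and polyfluoroalkyl substances (PFAS), fluorinated chemicals with differing chain lengths and head groups. The title of the series names points of departure as its aim, that is, the concentrations at which expression begins to change. The 460 treated libraries covered 7 nominal concentrations per compound, 0.1, 0.3, 1, 3, 10, 32 and 100 µM, or 0.005 to 5 µM for PFTrDA. Each concentration had 3 libraries, except 100 µM of PFHpA and of 6:1 FTOH with 2 each. The 11 exposures each tested 2 compounds beside 3 DMSO control libraries, 33 in all. The total count per library had a median of 1161621. The exposure with PFNA and PFTrDA was the shallowest, with a median total of 382721, followed by that with PFTeDA and PFUdA at 658987; medians of the others lay between 1062230 and 1436020.

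At the highest concentration, the number of genes that differed from the control (edgeR, adjusted p under 0.05) ranged from 15 to 5340. FC10diol at 100 µM moved 5340 of 9122 tested genes, 2609 up and 2731 down, and 3792 of them changed at least 2-fold. PFTDoDA raised 1179 genes and lowered 1037. PFTP raised 1003 and lowered 726, and FHxSA, the perfluorohexane sulfonamide, raised 673 and lowered 787. FC8diol raised 474 and lowered 434, and N-EtFOSA-M raised 303 and lowered 387. Changes with FHxSA were small, with a median size of 0.62 on the log2 scale and 218 genes past 2-fold, whereas those with FC10diol had a median size of 1.44. Without scaling factors the median gene of FC10diol shifted from -0.06 to -0.45 on the log2 scale, and the share of rises went from 48.9% to 32.5%. The same change of scaling moved the share of rises from 52.2% to 36% with FC8diol and from 58% to 40.3% with PFTP, where the median gene shifted from -0.02 to -0.14. The direction of most genes with these 3 compounds is therefore stated relative to the TMM scale.

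Perfluorinated carboxylic acids and sulfonates gave smaller counts. At 100 µM, PFOS, the sulfonate with an 8-carbon chain, raised 242 genes and lowered 185. PFHxS, the shorter sulfonate, raised 250 and lowered 165. PFOA raised 142 and lowered 88, PFUdA raised 93 and lowered 135, PFNA raised 47 and lowered 48, PFTeDA raised 38 and lowered 35, PFPeA raised 31 and lowered 47, and PFHpA raised 6 and lowered 9. PFTrDA at 5 µM raised 10 and lowered 5. The fluorotelomer sulfonates raised 33, 83 and 96 genes and lowered 41, 95 and 154 for 4:2FTS, 6:2FTS and 8:2FTS. 6:1 FTOH changed 238 genes, PFPB 128, FC8DoD 70 and PF4OPeA 16. All these counts leave the replicate number out of the fit. With it as a covariate, 14 of the 22 compounds' counts rose by over 1.5 times. FC8DoD then had 299, PFHxS 843 and PF4OPeA 254. The 70 and 16 of FC8DoD and PF4OPeA thus do not show a weak response. With DESeq2 the share of rises was 31.2% for 4:2FTS and 28.3% for PFHpA, against 44.6% and 40% with edgeR. Without DMSO replicate 3 of their exposure, PFOA changed 733 genes and PFOS 1395, against 230 and 427 with all 3 controls. Without DMSO replicate 1 the counts were 65 and 213, and without DMSO replicate 2 they were 105 and 211. Leaving out replicate number 2 from every group lowered 21 of the 22 compounds' counts by over 1.5 times, among them N-EtFOSA-M to 99, 6:1 FTOH to 31 and PFOA to 14. FC10diol was the exception, with 4378 genes.

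The number of changed genes rose with concentration for some compounds and not for others. With FC10diol it was 19 at 0.1 µM, 285 at 3 µM, 1321 at 10 µM and 2125 at 32 µM. With PFTDoDA it was 76 at 0.1 µM, 276 at 10 µM and 806 at 32 µM. N-EtFOSA-M changed 83 genes at 10 µM and 321 at 32 µM, and FHxSA changed 84 at 0.1 µM, 626 at 10 µM and 1207 at 32 µM. PFUdA went from 5 genes at 0.1 µM to 110 at 3 µM and 189 at 32 µM. PFHxS changed 87 genes at 0.1 µM, 536 at 10 µM and 415 at 100 µM, and PFTP already changed 104 at 0.1 µM. At 0.1 µM PFTP and PF4OPeA, which share controls, differed in 0 genes by edgeR (754 at an unadjusted p under 0.05). PFHxS and FC8DoD also differed in 0 there (683). PF4OPeA and FC8DoD had 0 genes against the control at 0.1 µM. The 104 and 87 genes are thus not shown to be particular to PFTP and PFHxS. At 10 µM, 1437 genes changed with PFHpA, 1736 with PFPeA, 1527 with PFPB and 1369 with 6:1 FTOH, but 2, 36, 46 and 47 changed at 32 µM.

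**Figure D1:**
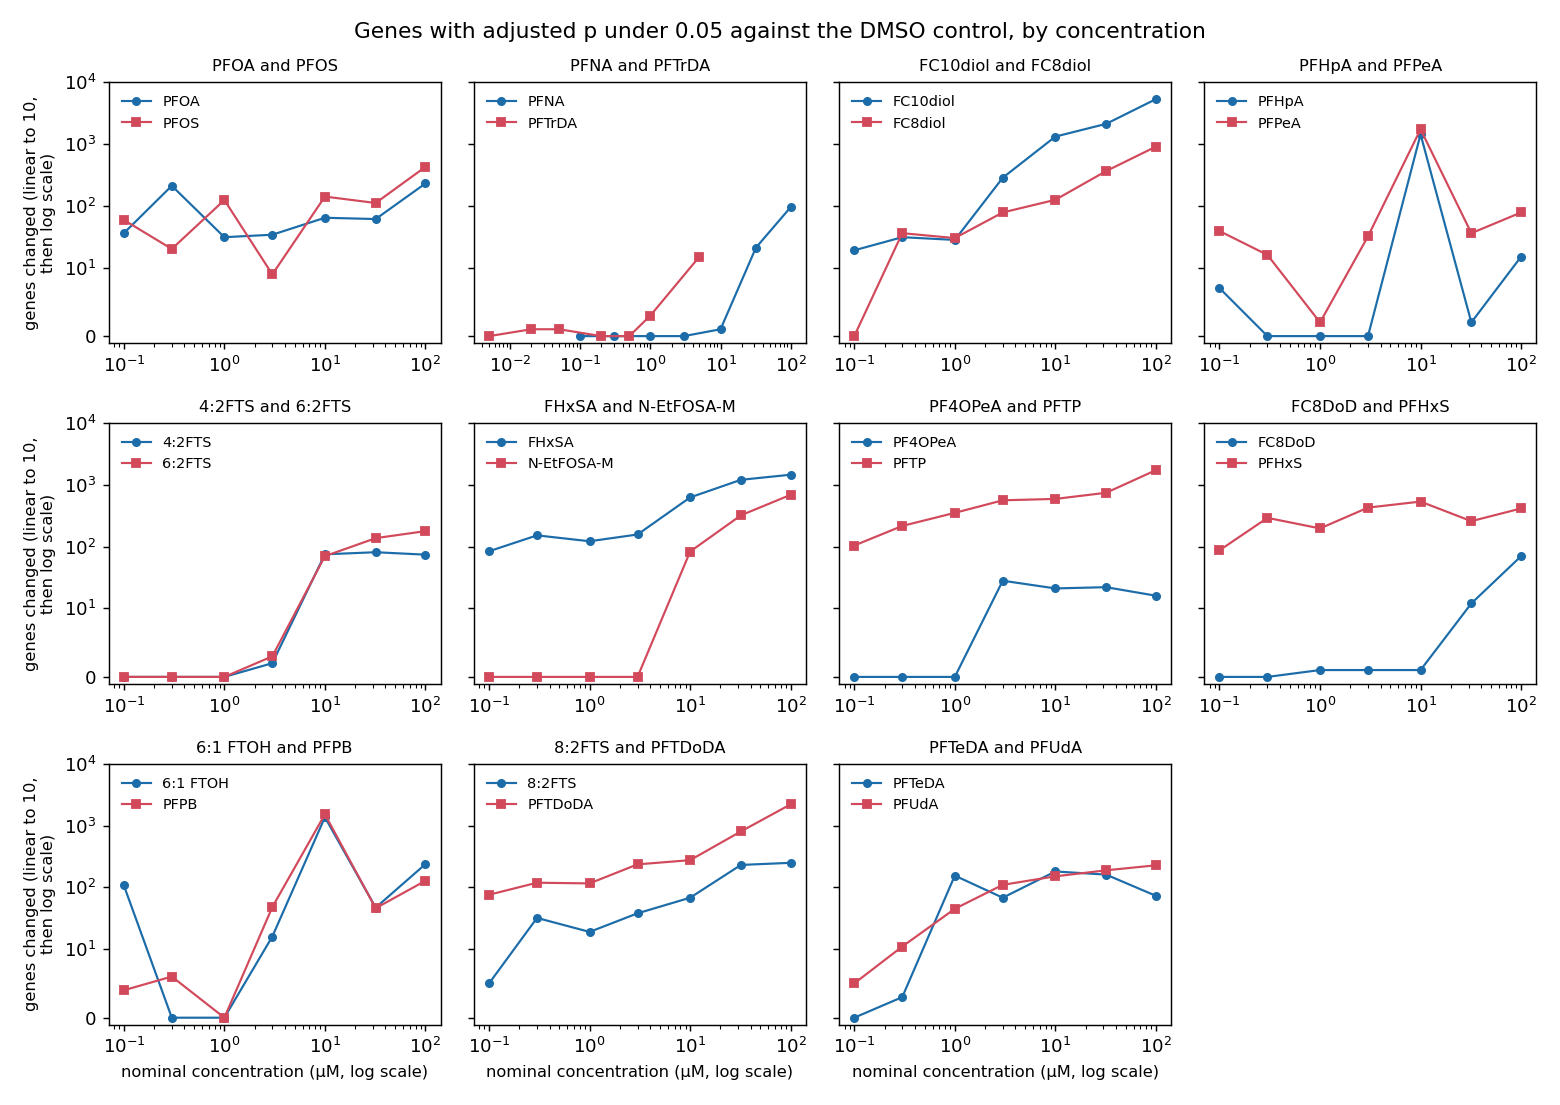
Number of genes with an adjusted p under 0.05 against the DMSO control (vertical axis, linear up to 10 and logarithmic above) at each nominal concentration in µM (horizontal log axis), one panel per exposure and one line per compound. FC10diol rises to 5340 genes at 100 µM, and PFHpA, PFPeA, PFPB and 6:1 FTOH peak at 10 µM.

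The contrast of the highest with the lowest concentration of the same compound does not use the control. FC10diol differed in 5389 genes, of which 4753 were also called against the control, and PFTDoDA differed in 2259, with 1568 shared. For FC8diol the count was 890 and for N-EtFOSA-M 575. It was 1134 for PFTP and 767 for FHxSA, lower than against the control. PFHxS differed in 2 genes, against 415 with the control, PFOA in 27 against 230, 6:2FTS in 31 against 178 and PF4OPeA in 1 against 16. PFHpA differed in 310 genes, PFPB in 583, 6:1 FTOH in 421, PFUdA in 325 and 4:2FTS in 138, more than against the control. For 6:1 FTOH the reference at 0.1 µM itself differed from the control in 108 genes, against 0 at 0.3 and at 1 µM.

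Some genes moved in most exposures. Counting exposures and not compounds, 78 genes rose in at least 5 of the 11, where random lists of the same sizes gave a mean of 3.5 and at most 11. Falls in at least 5 exposures were seen for 52 genes, against a mean of 5.8 and at most 13. The draws matched mean expression but not the spread between libraries, so genes with a small spread could also recur beyond them. Recurrence was counted against the controls only, and not from the lowest concentration. Rsub_07992 rose in 10 exposures and with 15 of 22 compounds. Its level went from 158.8 ± 6.5 CPM (counts scaled to the library total; SD, n = 3) in the control to 5574.7 ± 305.5 (SD, n = 3) with FC10diol, a log2 fold change of 5.53 (SE 0.12, edgeR adjusted p = 2.5e-31). It also rose by 3.26 with PFTDoDA, 2.47 with PFUdA and 1.74 with PFOS on the log2 scale. Rsub_09510 rose in 10 exposures and with 18 compounds, from 115.7 ± 10.2 to 5444.9 ± 389.6 CPM (SD, n = 3 each) with FC10diol, a log2 fold change of 5.95 (SE 0.14, edgeR adjusted p = 3.4e-30). With FC8diol it rose by 3.35, with 6:1 FTOH by 2.26 and with PFOS by 2.11. Its control level varied widely between exposures, from 115.7 CPM in that of FC10diol to 1199.6 CPM in that of PFTeDA and PFUdA. The largest fold thus came from the exposure with the lowest control. With PFPeA and PFHpA it was called as a rise at 322.9 and 289.7 CPM, below the controls of several other exposures.

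Rsub_11220 fell in 8 exposures and with 11 compounds. With FC8diol it went from 202.7 ± 10.6 to 13.7 ± 6.9 CPM (SD, n = 3 each), a log2 fold change of -3.74 (SE 0.21, edgeR adjusted p = 6.1e-18). It fell by 3.04 with PFTDoDA and fell by 2.55 with PFOS. Rsub_04475 fell in 8 exposures and with 9 compounds, and with FC8diol it went from 120.8 ± 19.1 to 13.4 ± 3.9 CPM (SD, n = 3 each), a log2 fold change of -3.06 (SE 0.25, edgeR adjusted p = 1.1e-12). With FC10diol its mean fell to 0.3 counts per library, too few for a fold. Without replicate number 2, the genes that rose in at least 5 exposures numbered 22 and those that fell numbered 6.

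**Figure D2:**
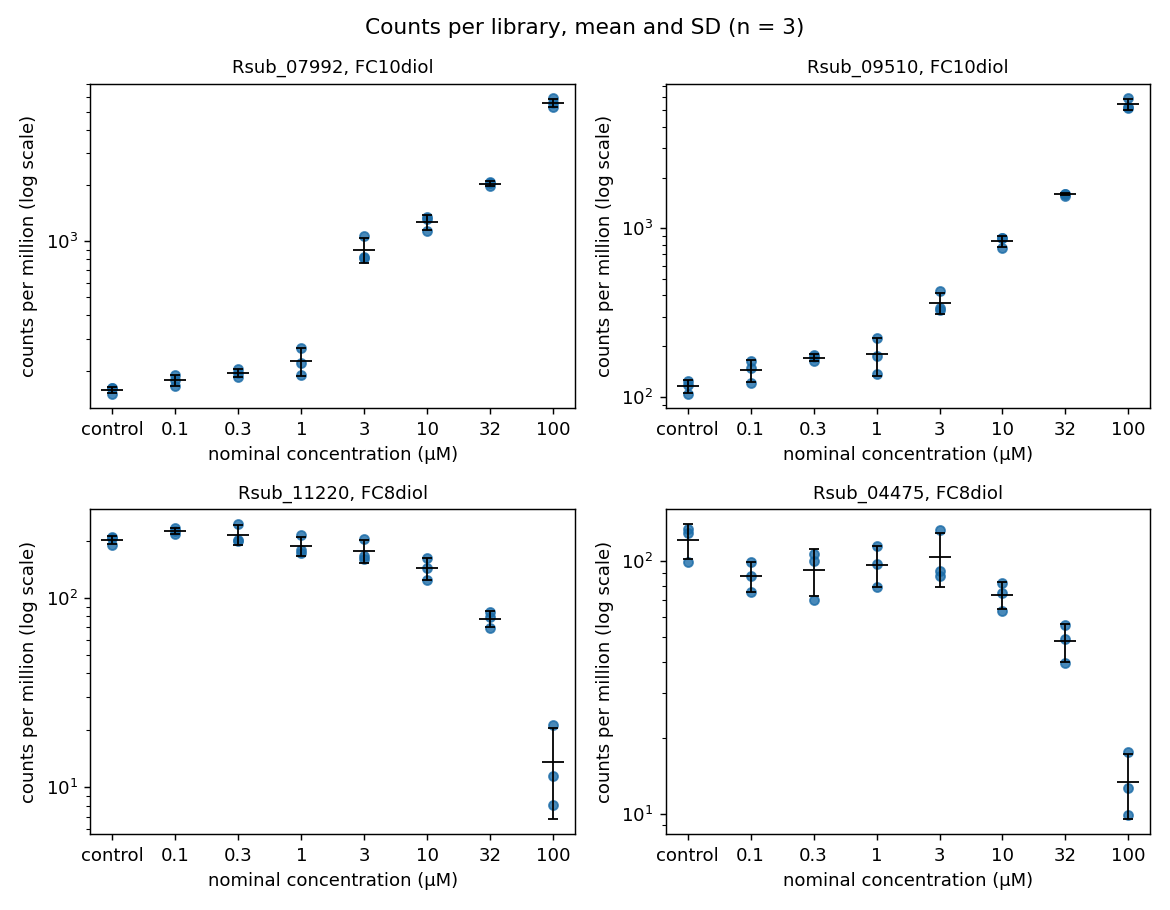
Counts scaled to the library total, as CPM (vertical log axis) of the 4 named genes in each library (points) at each nominal concentration in µM, with the mean and SD of 3 libraries (black marks). Rsub_07992 and Rsub_09510 climb from 3 µM of FC10diol on, and Rsub_11220 and Rsub_04475 drop at 32 and 100 µM of FC8diol.

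A trend over the ranked concentrations was found for 18 to 3892 genes per compound (edgeR). FC10diol had 3892 (2245 up, 1647 down), PFTDoDA 2118, FHxSA 1931, PFTP 1707, FC8diol 1482 and N-EtFOSA-M 1286. PFUdA had 708, PFPB 626, 4:2FTS 544, PFOS 280 and PFOA 81. Without the control libraries the trend counts were 3842 for FC10diol, 2133 for PFTDoDA and 1411 for FHxSA. They were 16 for PFHxS in place of 314, 43 for PF4OPeA in place of 484, 42 for 6:2FTS in place of 264 and 42 for PFTeDA in place of 150. Without replicate number 2, 21 of the 22 trend counts were lower by over 1.5 times, among them 4:2FTS with 158 and PF4OPeA with 76; FC10diol had 2749. For PFPeA, with 229 genes, 2 of 25 splits of the libraries gave as many.

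Points of departure could be computed for 21 compounds and lay between 0.0255 and 1.89 µM. They come from curves over all concentrations and need not match the concentrations where genes were called against the control. PFNA had 0 genes called at 1 and at 3 µM and 1 at 10 µM, and N-EtFOSA-M had 0 at 3 µM. In the other direction, FC10diol had 19 genes called at 0.1 µM already. The order depends on the definition. Taking the 25th lowest gene moved 10 values lower and 6 higher, with FC10diol and N-EtFOSA-M then below 0.1 µM. Taking the median gene moved all 21 higher. By the 10th percentile the highest were 1.89 µM for FC10diol (95% interval 1.72 to 2.08 µM, 3706 genes), 1.11 µM for N-EtFOSA-M (0.919 to 1.32 µM) and 0.828 µM for PFNA (0.247 to 2.38 µM). PFPB, 6:1 FTOH, 4:2FTS, PFTDoDA and PFHpA followed at 0.499, 0.465, 0.416, 0.412 and 0.361 µM. FC8DoD had 0.314, PF4OPeA 0.264, PFUdA 0.244, FC8diol 0.177, PFPeA 0.163 and PFTeDA 0.111 µM. For 7 compounds the value fell below the lowest tested concentration of 0.1 µM and is an extrapolation: 6:2FTS at 0.0733, 8:2FTS at 0.0704, FHxSA at 0.048, PFTP at 0.0398, PFOS at 0.0321, PFHxS at 0.0307 and PFOA at 0.0255 µM. Fitting without the control libraries moved 12 compounds by over 3-fold. PFOA then came to 5.89 µM, PFOS to 4.28 µM, FHxSA to 0.993 µM and 6:2FTS to 0.663 µM, whereas PFHpA fell to 0.0183 µM. That value is an extrapolation below 0.1 µM, as are 0.0682 µM for 6:1 FTOH and 0.098 µM for PFTP without controls. In these fits the 1.5-fold filter was taken from the lowest concentration, so their values are not fully comparable with those from the controls. PFHxS then had no value, and FC10diol and N-EtFOSA-M had 2.25 and 0.958 µM. PFTrDA, without a value when the controls were used, had 0.102 µM from 21 genes without them. PFOA had the lowest value with the controls and the highest without them. Without the 10 µM libraries PFPeA came to 0.0514 µM, below the lowest tested concentration, PFHpA to 0.185 µM and PFPB to 0.294 µM. When each replicate number was left out, the values of PFOA ranged from 0.0103 to 0.516 µM, PFOS from 0.00724 to 0.551 µM, 6:2FTS from 0.0307 to 0.106 µM and 8:2FTS from 0.0487 to 0.114 µM. These 4 compounds thus lay below or above the lowest tested concentration depending on the libraries used. PFNA ranged from 0.142 to 1.33 µM, N-EtFOSA-M from 0.638 to 1.18 µM, 4:2FTS from 0.252 to 0.654 µM, PFPB from 0.307 to 0.553 µM and FC8diol from 0.17 to 0.347 µM. FC8DoD ranged from 0.194 to 0.34 µM, PFUdA from 0.141 to 0.31 µM, PF4OPeA from 0.167 to 0.197 µM and PFTeDA from 0.116 to 0.17 µM. PFPeA ranged from 0.103 to 0.158 µM with no value without replicate number 2, and PFHpA had none without replicate number 3.

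**Figure D3:**
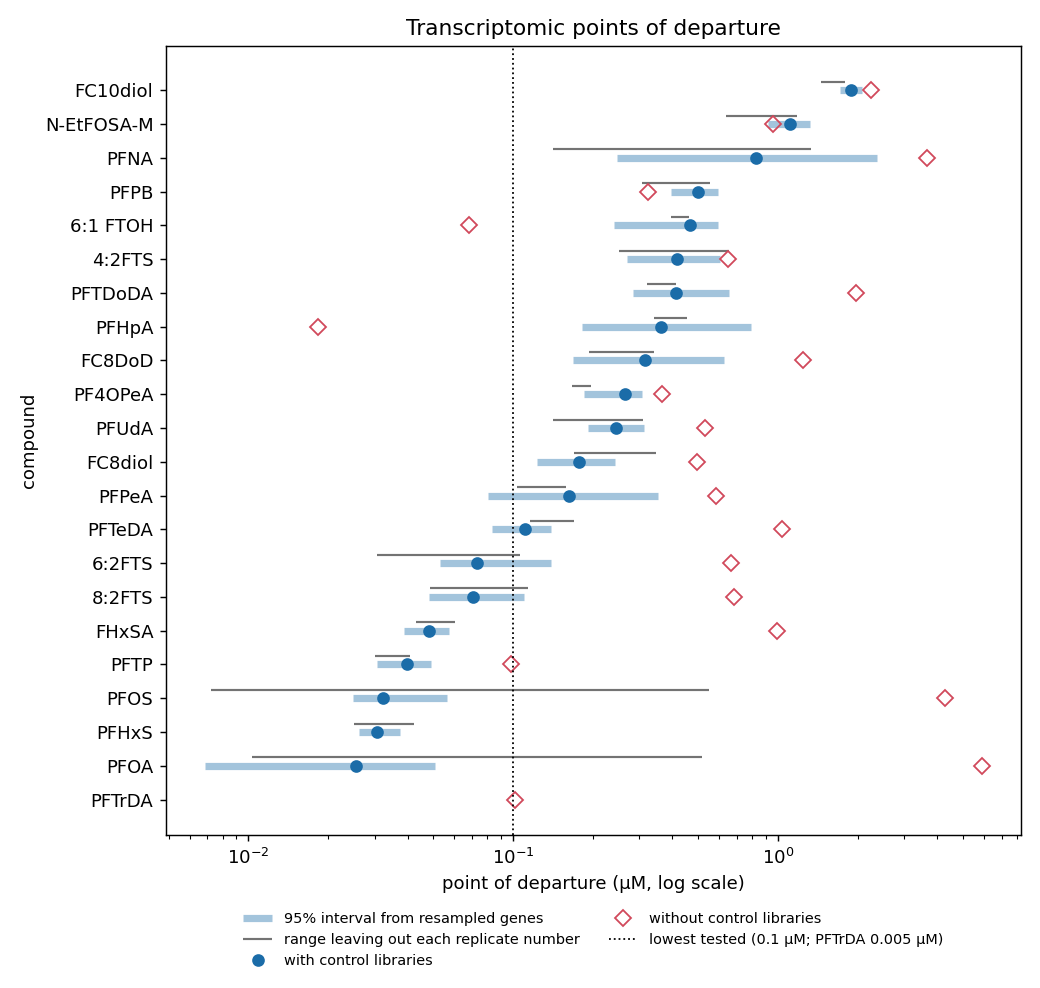
Point of departure in µM (horizontal log axis) of each compound, with the control libraries (filled points, thick bars for the 95% interval from resampled genes, thin lines for the range when each replicate number is left out) and without them (open diamonds, the only mark for PFTrDA). The dotted line marks 0.1 µM; 7 filled points lie below it, and PFOA moves from 0.0255 to 5.89 µM without controls.

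Compounds of one exposure were compared directly. FC10diol and FC8diol differed in 4997 genes at 100 µM, 2378 higher with FC10diol and 2619 lower, and 3438 differed at least 2-fold. 8:2FTS and PFTDoDA differed in 1603 genes, PF4OPeA and PFTP in 642, FHxSA and N-EtFOSA-M in 274 and FC8DoD and PFHxS in 206. The fluorotelomer sulfonates 4:2FTS and 6:2FTS, which differ in the length of the fluorinated chain, differed in 156 genes, 71 higher with 4:2FTS and 85 lower. 6:1 FTOH and PFPB differed in 87 genes. PFOA and PFOS, with 8 carbons each and a carboxylate or sulfonate head group, differed in 7 genes, 1 higher with PFOA and 6 lower. The median over genes of the unadjusted 95% half-width of that difference was 0.55 on the log2 scale, and genes that were not called are not shown to be equal. PFTeDA and PFUdA differed in 9 genes, and PFNA and PFTrDA in 3 at 1 µM, the highest concentration both had. PFHpA and PFPeA, acids of 7 and 5 carbons, differed in 0 genes by edgeR, with 202 of 9858 genes at an unadjusted p under 0.05 and a half-width of 0.74. These 202 are a smaller share than the 0.05 that equal levels alone would give. The test may thus have been too strict for this pair, for a reason that was not tested. No other tool was run on these contrasts.

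When each compound's change from its own lowest shared concentration was compared in place of the levels, FC10diol and FC8diol differed in 3857 genes, 8:2FTS and PFTDoDA in 993 and FHxSA and N-EtFOSA-M in 100. The counts were 9 for 4:2FTS and 6:2FTS, 64 for PF4OPeA and PFTP and 1 for FC8DoD and PFHxS. 6:1 FTOH and PFPB already differed in 433 genes at 0.1 µM. Without replicate number 2, 15 of the 17 pair counts, within and across exposures, were lower by over 1.5 times; that of 4:2FTS and 6:2FTS was 6.

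Related compounds from different exposures were compared by the difference of their changes against their own controls at 100 µM. PFHxS and the sulfonamide of the same chain length, FHxSA, differed in 975 genes, 585 with a higher change for PFHxS and 390 with a lower one. PFHxS and PFOS, sulfonates that differ in chain length, differed in 237 genes. 6:2FTS and 8:2FTS differed in 84. Among the carboxylic acids, PFNA and PFUdA differed in 62 genes, PFHpA and PFOA in 29 and PFOA and PFNA in 27. Typical 95% half-widths lay between 0.73 and 1.06 on the log2 scale. Without replicate number 2 the count was 15 for PFHxS and PFOS, and without replicate number 3 it was 501. For PFOA and PFNA 4 of 25 splits of the libraries gave as many genes, and for PFNA and PFUdA 2 of 25 did. Measured from the lowest concentration in place of the control, the difference was 74 genes for PFHxS and FHxSA, 19 for PFHxS and PFOS, 10 for 6:2FTS and 8:2FTS and 91 for PFHpA and PFOA.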

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

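The contrasts at 0.1 µM, the differences of changes from the lowest concentration and the counts over other splits of the libraries were chosen after the results were seen; the contrasts at the highest concentration and the tests of the PFHxS pattern were set before their results were seen.

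Compounds of one exposure, and related compounds of different exposures, were singled out where a test of their difference called genes. Within exposures at 100 µM these were 7 genes for PFOA and PFOS, 4997 for FC10diol and FC8diol, 156 for 4:2FTS and 6:2FTS and 274 for FHxSA and N-EtFOSA-M. The counts were 642 for PF4OPeA and PFTP, 206 for FC8DoD and PFHxS, 87 for 6:1 FTOH and PFPB, 1603 for 8:2FTS and PFTDoDA and 9 for PFTeDA and PFUdA. PFNA and PFTrDA differed in 3 genes at 1 µM. At 0.1 µM the counts were 14 for PFOA and PFOS, 1 for FC10diol and FC8diol, 26 for PFHpA and PFPeA, 2 for 4:2FTS and 6:2FTS and 8 for FHxSA and N-EtFOSA-M. They were 433 for 6:1 FTOH and PFPB and 42 for 8:2FTS and PFTDoDA at that concentration. By edgeR, PF4OPeA and PFTP, FC8DoD and PFHxS, and PFTeDA and PFUdA had 0 there. Genes at an unadjusted p under 0.05 numbered 754, 683 and 742 for these pairs. Across exposures at 100 µM the changes differed in 237 genes for PFHxS and PFOS, 29 for PFHpA and PFOA, 27 for PFOA and PFNA, 62 for PFNA and PFUdA, 84 for 6:2FTS and 8:2FTS and 975 for PFHxS and FHxSA.

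Splits were counted at the highest shared concentration, for pairs with 3 libraries of each compound. 6:1 FTOH and PFHpA had 2 libraries at 100 µM, so no splits were counted for 6:1 FTOH and PFPB or for PFHpA and PFOA, nor for any pair at 0.1 µM. For the other pairs within an exposure, 3 libraries against 3 give 10 splits, too few for a share under 0.05. The highest count over the other splits was 10 for FC10diol and FC8diol, 11 for 8:2FTS and PFTDoDA, 3 for PF4OPeA and PFTP and 2 each for PFOA and PFOS and for 4:2FTS and 6:2FTS. For the other 5 pairs across exposures 25 splits were drawn. Those other than the real one exchanged treated and control libraries within 1 or both exposures. They ask whether a random grouping gives as many genes, and cannot tell whether the changes of 2 compounds are equal. Only the real split, 1 of 25 and the lowest share possible, reached the count for 3 pairs. These were PFHxS and PFOS (highest other 54), 6:2FTS and 8:2FTS (highest other 33) and PFHxS and FHxSA (highest other 254). A random grouping was not excluded for PFOA and PFNA, where 4 of 25 splits gave as many as 27 genes and the highest other gave 83. Nor was it for PFNA and PFUdA, where 2 of 25 splits gave as many as 62 and the highest other gave 70.

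PFHxS differed from the control at every concentration, in 87 genes at 0.1 µM and 415 at 100 µM, but 2 genes differed between those concentrations. A difference in depth was argued against, since 84.3% as many genes were called after thinning all libraries to the smallest total of the table. Control libraries standing apart from all others of the exposure may contribute: the PFHxS genes moved 0.46 times as far in FC8DoD, which shares the controls, with 0.23 to 0.67 over its concentrations. That value lies under the bound of 0.5 set beforehand against this explanation, but by less than its spread. The spread was added to the rule after the value was seen, which changed the verdict from excluded to undecided. The bound itself cannot decide, since both changes subtract the same controls and chance deviations of these alone could give a value near 0.5. At 0.1 µM, FC8DoD and PFHxS differed in 0 genes by edgeR (683 at an unadjusted p under 0.05). A response nearly complete at the lowest concentration (median change at 0.1 µM 0.56 times that at 100 µM) and a shared plate position of one compound's wells (median absolute correlation of 0.18 between exposures) likewise remain undecided.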

How the results depend on the processing

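The alternatives without control libraries, without 10 µM libraries, against the lowest concentration, without single DMSO libraries, with differences of changes for the pairs, with library totals and all those of the recurrence, and the replicate block of the points of departure and of the 10 µM contrast, were chosen after seeing the data; the others were fixed beforehand. Each changed 1 choice and kept the rest, except DESeq2, which brings its own size factors and its own filter on low counts along with its test. A count was taken as unmoved within 1.5 times its value, and a point of departure when its log value moved by less than 1 SD of the log values obtained by leaving out each replicate number. That SD differs between compounds, so small moves are listed for FC10diol, while larger ones are not for others: 4:2FTS came to 0.651 µM without controls in place of 0.416, and with a benchmark response of 2 SD PFOA came to 0.0704 in place of 0.0255 and PFOS to 0.0877 in place of 0.0321. The cause of the moves was not tested, except that leaving out a replicate number leaves fewer libraries. RLE size factors and library totals left the 22 counts at the highest concentration within 1.5 times, and RLE size factors and no filter did so for the 22 trend counts. With 1 compound each, FC10diol for Rsub_07992 and Rsub_09510 and FC8diol for Rsub_11220 and Rsub_04475, the 4 named genes kept their direction and their call with RLE size factors, without the filter, with DESeq2, with the block and without each replicate number. With the other compounds only the block was examined gene by gene, and it ended no call and added 7. These were Rsub_07992 with FC8DoD (edgeR adjusted p 0.13 without and 0.01 with the block), Rsub_09510 with 4:2FTS (0.39 and 0.012) and PFUdA (0.086 and 0.018) and Rsub_04475 with FHxSA (0.12 and 0.047) and PFHxS (0.097 and 0.029). Rsub_11220 was added with FC8DoD (0.43 and 0.013) and with PFTP (0.59 and 0.049), where its log2 fold change without the block was 0.26, opposite to its falls. FC10diol stayed between 4378 and 4841 genes when each replicate number was left out. No library total was under 20% of its table's median, so the planned removal of shallow libraries changed nothing, and the gene lists had no matched genes, so their alternatives were not run. PFTrDA had no point of departure with the controls (0.102 µM without them), PFHxS had none without controls, and PFHpA and PFPeA each had none without 1 of the replicate numbers. In the simulations at the highest concentration, which covered PFNA and FHxSA, 28.4% of 2-fold changes were recovered for PFNA and 74.6% for FHxSA. Their exposures had median totals of 382721 and 1332132 counts, and their median biological coefficients of variation also differed, at 0.21 and 0.14.

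No label says that a replicate number marks a shared plate or culture across groups. Of 64 pairs of a control and a highest-concentration library with the same number, 7 had deviations from their group means that correlated above 0.1, with a median of 0.04, and no compound had all its pairs above 0.1. On this check of the groups compared, the numbers were not taken as pairing the libraries, and this was decided after counts with the replicate block had been seen. Other values go against it. Over all exposures, 431 of 493 libraries correlated best with others of their own number, where each could match any of 3 numbers. Between the control and the mean of the other groups, 30 of 66 pairs were above 0.1, with a median of 0.09. All 3 numbers were above 0.1 in that comparison for FC8DoD (0.41, 0.17 and 0.32), PFHxS (0.29, 0.11 and 0.16), PF4OPeA (0.23, 0.13 and 0.21) and PFTP (0.17, 0.17 and 0.12). The numbers may thus mark shared handling, in these 2 exposures and, by the count of libraries, in others too. The counts with the block, 299 for FC8DoD, 843 for PFHxS and 254 for PF4OPeA, would then account for it. The replicate block moved 14 of 22 counts at the highest concentration, all upward. With the block the counts were 4:2FTS 166 in place of 74, 6:1 FTOH 470 in place of 238, 6:2FTS 483 in place of 178, 8:2FTS 460 in place of 250, FC8DoD 299 in place of 70, N-EtFOSA-M 1060 in place of 690 and PF4OPeA 254 in place of 16. PFHxS gave 843 in place of 415, PFNA 158 in place of 95, PFOA 402 in place of 230, PFPB 225 in place of 128, PFPeA 227 in place of 78, PFTeDA 131 in place of 73 and PFUdA 387 in place of 228. Trend counts with the block were 6:2FTS 502 in place of 264, FC8DoD 624 in place of 271, PF4OPeA 785 in place of 484, PFHxS 596 in place of 314, PFOA 152 in place of 81 and PFTrDA 29 in place of 18. Points of departure (µM) with the block were 6:1 FTOH 0.226 in place of 0.465, 6:2FTS 0.0349 in place of 0.0733, PF4OPeA 0.188 in place of 0.264, PFHpA 0.606 in place of 0.361, PFHxS 0.0203 in place of 0.0307, PFTDoDA 0.348 in place of 0.412 and PFTeDA 0.0878 in place of 0.111. For compound pairs of an exposure the block gave PFOA/PFOS 35 in place of 7, 4:2FTS/6:2FTS 311 in place of 156, PF4OPeA/PFTP 1041 in place of 642, FC8DoD/PFHxS 394 in place of 206, 6:1 FTOH/PFPB 146 in place of 87 and PFTeDA/PFUdA 16 in place of 9. Across exposures the block gave PFHxS/PFOS 535 in place of 237, PFHpA/PFOA 56 in place of 29, PFOA/PFNA 48 in place of 27, PFNA/PFUdA 119 in place of 62 and 6:2FTS/8:2FTS 351 in place of 84. Of the recurring genes, the block gave for rises in at least 5 exposures 146 in place of 78 and falls in at least 5 exposures 174 in place of 52. The contrast of 10 µM with 3 and 32 µM gave for 6:1 FTOH 1047 in place of 683. The block left 0 genes for PFHpA/PFPeA in edgeR, as did the fit without it (308 and 202 genes at an unadjusted p under 0.05).

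Without the filter the counts at the highest concentration were 4:2FTS 170 in place of 74, 6:2FTS 436 in place of 178, PF4OPeA 38 in place of 16, PFHpA 52 in place of 15 and PFTeDA 122 in place of 73. By DESeq2 they were 4:2FTS 125 in place of 74, 6:1 FTOH 367 in place of 238, FC8DoD 109 in place of 70, PF4OPeA 119 in place of 16, PFHpA 46 in place of 15, PFPB 193 in place of 128 and PFPeA 182 in place of 78. Against the lowest concentration they were 4:2FTS 138 in place of 74, 6:1 FTOH 421 in place of 238, 6:2FTS 31 in place of 178, 8:2FTS 163 in place of 250, FHxSA 767 in place of 1460, PF4OPeA 1 in place of 16 and PFHpA 310 in place of 15. PFHxS gave 2 in place of 415, PFOA 27 in place of 230, PFOS 205 in place of 427, PFPB 583 in place of 128, PFTeDA 41 in place of 73 and PFTP 1134 in place of 1729. Recurring genes without the filter were, for falls in at least 5 exposures 93 in place of 52. RLE size factors gave for PFNA/PFTrDA 1 in place of 3. Without the 10 µM libraries the count was, for PF4OPeA 8 in place of 16. Trend counts without these libraries were 4:2FTS 342 in place of 544, 6:1 FTOH 304 in place of 509, PFNA 86 in place of 130 and PFUdA 448 in place of 708. Points of departure (µM) without them were 6:1 FTOH 0.425 in place of 0.465, PFHpA 0.185 in place of 0.361, PFPB 0.294 in place of 0.499 and PFPeA 0.0514 in place of 0.163. Trend counts without the control libraries were 6:2FTS 42 in place of 264, PF4OPeA 43 in place of 484, PFHxS 16 in place of 314, PFPeA 127 in place of 229, PFTeDA 42 in place of 150 and PFTrDA 30 in place of 18. Points of departure (µM) without controls were 6:1 FTOH 0.0682 in place of 0.465, 6:2FTS 0.663 in place of 0.0733, 8:2FTS 0.684 in place of 0.0704, FC10diol 2.25 in place of 1.89, FC8diol 0.497 in place of 0.177, FC8DoD 1.24 in place of 0.314 and FHxSA 0.993 in place of 0.048. PF4OPeA gave 0.365 in place of 0.264, PFHpA 0.0183 in place of 0.361, PFNA 3.67 in place of 0.828, PFOA 5.89 in place of 0.0255, PFOS 4.28 in place of 0.0321, PFPB 0.324 in place of 0.499 and PFPeA 0.585 in place of 0.163. PFTDoDA gave 1.97 in place of 0.412, PFTeDA 1.04 in place of 0.111, PFTP 0.098 in place of 0.0398 and PFUdA 0.531 in place of 0.244. The values of 6:1 FTOH, PFHpA and PFTP without controls lie below their lowest tested concentration and are extrapolations.

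Taking the difference of changes from the lowest concentration, compound pairs gave 4:2FTS/6:2FTS 9 in place of 156, FHxSA/N-EtFOSA-M 100 in place of 274, PF4OPeA/PFTP 64 in place of 642, FC8DoD/PFHxS 1 in place of 206, 8:2FTS/PFTDoDA 993 in place of 1603 and PFTeDA/PFUdA 0 in place of 9. The 0 for PFTeDA/PFUdA came from edgeR, with 467 genes at an unadjusted p under 0.05. Pairs across exposures gave PFHxS/PFOS 19 in place of 237, PFHpA/PFOA 91 in place of 29, PFOA/PFNA 12 in place of 27, 6:2FTS/8:2FTS 10 in place of 84 and PFHxS/FHxSA 74 in place of 975.

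Points of departure (µM) from the 25th lowest gene were 6:1 FTOH 0.15 in place of 0.465, FC10diol 0.0443 in place of 1.89, FC8diol 0.0362 in place of 0.177, FC8DoD 0.476 in place of 0.314, FHxSA 0.0163 in place of 0.048, N-EtFOSA-M 0.0849 in place of 1.11 and PF4OPeA 0.218 in place of 0.264. PFHpA gave 0.904 in place of 0.361, PFNA 3.71 in place of 0.828, PFOA 0.3 in place of 0.0255, PFPB 0.172 in place of 0.499, PFPeA 0.246 in place of 0.163, PFTDoDA 0.0214 in place of 0.412 and PFTeDA 0.14 in place of 0.111. PFTP gave 0.00999 in place of 0.0398 and PFUdA 0.104 in place of 0.244. From the median gene they were 4:2FTS 2.01 in place of 0.416, 6:1 FTOH 1.94 in place of 0.465, 6:2FTS 1.71 in place of 0.0733, 8:2FTS 2.68 in place of 0.0704, FC10diol 21.2 in place of 1.89, FC8diol 7.73 in place of 0.177 and FC8DoD 6.41 in place of 0.314. FHxSA gave 3.96 in place of 0.048, N-EtFOSA-M 6.69 in place of 1.11, PF4OPeA 0.83 in place of 0.264, PFHpA 1.63 in place of 0.361, PFHxS 0.618 in place of 0.0307, PFNA 10.2 in place of 0.828 and PFOA 11.5 in place of 0.0255. PFOS gave 12.8 in place of 0.0321, PFPB 1.8 in place of 0.499, PFPeA 1.49 in place of 0.163, PFTDoDA 16.5 in place of 0.412, PFTeDA 0.484 in place of 0.111, PFTP 1.82 in place of 0.0398 and PFUdA 2.33 in place of 0.244. A fold filter of 2 gave 6:1 FTOH 0.24 in place of 0.465, FC10diol 2.35 in place of 1.89, FC8diol 0.327 in place of 0.177, FHxSA 0.0355 in place of 0.048, PF4OPeA 0.237 in place of 0.264, PFHpA 0.194 in place of 0.361 and PFPB 0.344 in place of 0.499. PFTDoDA gave 0.472 in place of 0.412 and PFTP 0.0261 in place of 0.0398. A benchmark response of 2 SD gave 4:2FTS 1.07 in place of 0.416, 6:1 FTOH 1.06 in place of 0.465, 6:2FTS 0.206 in place of 0.0733, 8:2FTS 0.175 in place of 0.0704, FC10diol 5.43 in place of 1.89, FC8diol 0.393 in place of 0.177 and FC8DoD 0.86 in place of 0.314. FHxSA gave 0.109 in place of 0.048, N-EtFOSA-M 2.71 in place of 1.11, PF4OPeA 0.596 in place of 0.264, PFHpA 0.915 in place of 0.361, PFHxS 0.0723 in place of 0.0307, PFNA 8.8 in place of 0.828 and PFPB 1.2 in place of 0.499. PFPeA gave 0.365 in place of 0.163, PFTDoDA 1.31 in place of 0.412, PFTeDA 0.272 in place of 0.111, PFTP 0.0797 in place of 0.0398 and PFUdA 0.622 in place of 0.244.

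When each replicate number was left out in turn, and single DMSO libraries for PFOA and PFOS, the lowest and highest values were as follows. Where this left 1 library of PFHpA or 6:1 FTOH at 100 µM, that library was assumed to vary like the other groups. Counts at the highest concentration ran, for 4:2FTS 15 to 108 (all libraries 74), 6:1 FTOH 31 to 450 (all libraries 238), 6:2FTS 61 to 132 (all libraries 178), 8:2FTS 50 to 323 (all libraries 250) and FC8diol 353 to 1026 (all libraries 908). FC8DoD ran from 25 to 46 (all libraries 70), FHxSA 758 to 952 (all libraries 1460), N-EtFOSA-M 99 to 572 (all libraries 690), PF4OPeA 0 to 51 (all libraries 16) and PFHpA 0 to 25 (all libraries 15). PFHxS ran from 74 to 373 (all libraries 415), PFNA 48 to 76 (all libraries 95), PFOA 14 to 764 (all libraries 230), PFOS 58 to 1395 (all libraries 427) and PFPB 19 to 91 (all libraries 128). PFPeA ran from 7 to 70 (all libraries 78), PFTDoDA 1118 to 2230 (all libraries 2216), PFTeDA 24 to 37 (all libraries 73), PFTP 775 to 1259 (all libraries 1729) and PFTrDA 1 to 9 (all libraries 15). PFUdA ran from 103 to 163 (all libraries 228). The 0 of PF4OPeA without replicate 2 and of PFHpA without replicate 3 came from edgeR, with 848 and 424 genes at an unadjusted p under 0.05. Summed over compounds, trend counts ran from 8829 to 12387 (all libraries 17654). Singly they ran, for 4:2FTS 105 to 504 (all libraries 544), 6:1 FTOH 152 to 243 (all libraries 509), 6:2FTS 83 to 163 (all libraries 264), 8:2FTS 145 to 467 (all libraries 494) and FC8diol 654 to 1466 (all libraries 1482). FC8DoD ran from 97 to 176 (all libraries 271), FHxSA 1184 to 1305 (all libraries 1931), N-EtFOSA-M 406 to 907 (all libraries 1286), PF4OPeA 76 to 282 (all libraries 484) and PFHpA 1 to 42 (all libraries 136). PFHxS ran from 53 to 264 (all libraries 314), PFNA 52 to 93 (all libraries 130), PFOA 23 to 139 (all libraries 81), PFOS 82 to 166 (all libraries 280) and PFPB 176 to 374 (all libraries 626). PFPeA ran from 15 to 215 (all libraries 229), PFTDoDA 1107 to 1846 (all libraries 2118), PFTeDA 31 to 116 (all libraries 150), PFTP 1009 to 1140 (all libraries 1707) and PFTrDA 11 to 21 (all libraries 18). PFUdA ran from 338 to 477 (all libraries 708).

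Points of departure (µM) ran, for 4:2FTS 0.252 to 0.654 (all libraries 0.416), 6:1 FTOH 0.396 to 0.462 (all libraries 0.465), 6:2FTS 0.0307 to 0.106 (all libraries 0.0733), 8:2FTS 0.0487 to 0.114 (all libraries 0.0704) and FC10diol 1.45 to 1.79 (all libraries 1.89). FC8diol ran from 0.17 to 0.347 (all libraries 0.177), FC8DoD 0.194 to 0.34 (all libraries 0.314), FHxSA 0.0428 to 0.0601 (all libraries 0.048), N-EtFOSA-M 0.638 to 1.18 (all libraries 1.11) and PF4OPeA 0.167 to 0.197 (all libraries 0.264). PFHpA ran from 0.341 to 0.455 (all libraries 0.361), PFHxS 0.0251 to 0.0422 (all libraries 0.0307), PFNA 0.142 to 1.33 (all libraries 0.828), PFOA 0.0103 to 0.516 (all libraries 0.0255) and PFOS 0.00724 to 0.551 (all libraries 0.0321). PFPB ran from 0.307 to 0.553 (all libraries 0.499), PFPeA 0.103 to 0.158 (all libraries 0.163), PFTDoDA 0.32 to 0.411 (all libraries 0.412), PFTeDA 0.116 to 0.17 (all libraries 0.111) and PFTP 0.03 to 0.0409 (all libraries 0.0398). PFUdA ran from 0.141 to 0.31 (all libraries 0.244). Pair counts ran, for PFOA/PFOS 3 to 19 (all libraries 7), PFNA/PFTrDA 0 to 3 (all libraries 3), 4:2FTS/6:2FTS 6 to 89 (all libraries 156), FHxSA/N-EtFOSA-M 79 to 241 (all libraries 274) and PF4OPeA/PFTP 157 to 393 (all libraries 642). FC8DoD/PFHxS ran from 37 to 121 (all libraries 206), 6:1 FTOH/PFPB 13 to 82 (all libraries 87), 8:2FTS/PFTDoDA 779 to 1382 (all libraries 1603) and PFTeDA/PFUdA 0 to 5 (all libraries 9). Pairs across exposures ran, for PFHxS/PFOS 15 to 501 (all libraries 237), PFHpA/PFOA 0 to 36 (all libraries 29), PFOA/PFNA 2 to 72 (all libraries 27), PFNA/PFUdA 14 to 21 (all libraries 62) and 6:2FTS/8:2FTS 13 to 82 (all libraries 84). PFHxS/FHxSA ran from 173 to 685 (all libraries 975). By edgeR, genes at an unadjusted p under 0.05 behind a count of 0 numbered 303 for PFNA/PFTrDA and 469 for PFHpA/PFOA without replicate 2, and for PFTeDA/PFUdA 244 without replicate 2 and 507 without replicate 3. PFHpA/PFPeA had 0 without each number, with 286, 133 and 241. Recurring genes ran, for rises in at least 5 exposures 22 to 67 (all libraries 78) and falls in at least 5 exposures 6 to 37 (all libraries 52).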

Other observations

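The tests of the 10 µM pattern other than thinning, the comparison of profiles between compounds and all counts over other splits were chosen after the results were seen; the thinning tests were set before theirs.

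Across genes, the changes with FC10diol and PFTDoDA at 100 µM resembled each other, although the compounds came from different exposures with different controls. Pearson's r was 0.59 and Spearman's rho 0.51 over 8967 genes, and r was 0.58 for changes from the lowest concentration. Both compounds raised 830 genes, where independent lists would share 322.3, and both lowered 689, where 307.8 would be shared. Opposite calls numbered 166, against 632.6. Among pairs from different exposures, the only pairs compared, the next by r was FC8diol with PFTDoDA at 0.31; for changes from the lowest concentration it was PFHpA with PFPB at 0.44. Genes are not independent replicates, so no p is given.

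At 10 µM, PFHpA, PFPeA, PFPB and 6:1 FTOH differed from the mean of 3 and 32 µM in 1356, 990, 1747 and 683 genes, while the other 17 compounds tested there had a median of 0 (edgeR) and at most 12. Depth was argued against, since 80.6% as many genes were called after thinning each table to its smallest total, and so was a plate position common to all layouts, by the median of 0 for the position of 10 µM in the other compounds. A response specific to each compound was argued against by correlations of the 10 µM shift across genes of at least 0.57 between the exposures. Genes called for this shift in the other exposure changed at 100 µM by at most 0.33 times their change at 10 µM. Their change thus did not grow with concentration. Being chosen for a peak at 10 µM, they cannot test a growing response in general. The values fit a common handling of these libraries, as a hypothesis: 12 of 12 had a 10 µM library as the closest in the other exposure, against 6 of 76 other libraries. A response shared by these compounds at 10 µM alone was not tested.

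Few genes were called for PFNA and PFTrDA, the shallowest tables. Thinning FC8diol, N-EtFOSA-M, PFOS and PFTDoDA to 361089 counts per library left 53.7% as many genes in all, between the bounds of 50% and 80% set beforehand for the sum. FC8diol went from 908 to 447, N-EtFOSA-M from 690 to 337 and PFOS from 427 to 205, each just below 50%, and PFTDoDA, which makes up most of the sum, from 2216 to 1289. Depth may account for part of the low counts of PFNA and PFTrDA and remains undecided. PFTrDA was also tested up to 5 µM only, against 100 µM for the other compounds, and the part of this in its low count was not tested.

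At the highest concentration, 3 libraries against 3 controls give 10 splits for 20 compounds, too few for a share under 0.05. No splits were counted for 6:1 FTOH (238 genes) and PFHpA (15 genes), which had 2 libraries there. The highest count over the other splits was 315 for PFOA, above its 230 (2 splits with as many), 224 for PFOS beside 427, 14 for PFTDoDA beside 2216 and 0 for FC10diol beside 5340. For the trends 25 splits were drawn, the real one included, and the others shuffled the ranks over control and treated libraries. Only the real one reached the count for 21 compounds, with no correction for their number. The shuffles moved single libraries and broke up the groups of replicates. They argue against a random assignment of ranks to libraries, but cannot show that the changes follow the order of concentration. Any difference between groups could give such a count, for instance controls or the libraries of 1 concentration that stand apart. Without controls the counts of PFHxS, PF4OPeA, 6:2FTS and PFTeDA fell to 16, 43, 42 and 42, while 16 of 22 stayed within 1.5 times. The highest other split was 863 for FC10diol beside 3892, 257 for FHxSA beside 1931 and 252 for PFPB beside 626. A random assignment of ranks was not argued against for PFPeA. There 2 of 25 splits gave as many as 229 genes, and the highest other gave 682, several times the real count. A count of that size points to some structure among these libraries, whose source was not tested. The 10 µM libraries of PFPeA differed from 3 and 32 µM in 990 genes, and whether they gave this count was not tested either.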
